A study of Equus caballus with 6 samples.

How the data were processed

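Total RNA of lamellar hoof tissue from 3 laminitis and 3 normal samples was made into biotin-labelled cRNA by oligo(dT) priming and a single round of linear amplification and hybridised to Affymetrix bovine GeneChips, per the labels' protocols. Samples were grouped by the sample titles, which also give the foot and a replicate number. How laminitis came about, and whether the samples are separate animals, is not given in the sources used here.

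The deposited values are linear intensities, 1 per probe set and array, scaled by the authors to a common level on every array. The mean after trimming 2% of probe sets at each end was 150.02 or 150.03 on each array, values ran from 0.0386 to 38469, and medians ran from 86.7 to 96.6. The submitters' processing notes name GCRMA, with its version not given, but a common trimmed mean and values far below 1 on a linear scale are features of a single scaling factor per array and not of GCRMA, which yields log2 values after quantile normalization. The step that made the values is therefore open, and they were used as they are. A single factor per array leaves differences between arrays that depend on brightness. Detection calls were not used here, so no value could be marked as not above background, and folds of genes dim in a group depend on that background.

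The bovine probes were read with horse RNA, so probe sets that mismatch the horse sequence read low or not at all, and signals of different probe sets are not compared. Gene symbols are bovine and come from GEO's platform annotation, which can be old. Of 24128 probe sets, 112 controls were left out. Of the remaining 24016, 13292 had 1 symbol, 86 several and 10638 none. Of 9155 symbols, 8624 are also a symbol or synonym in the horse RefSeq table of the TB-T2T assembly, which was used for this count only, and no coordinates are printed.

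Values were put on the log2 scale with no offset. A probe set was tested where it lay above its own array's median of non-control probe sets on at least 3 of 6 arrays, which left 12519 probe sets, of which 4909 had no single symbol. Laminitis was compared with normal tissue by lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05, and the prior had 3.02 degrees of freedom. The tested probe set with the highest mean over the 6 arrays stood for its gene, which gave 6151 genes. Errors of log2 differences are limma's standard errors, and folds are of geometric means. The values on each array were compared before averaging, and no pair of arrays shared identical values.

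The 35 gene lists, 13 of them markers of cell types, were fixed before the data were examined. Each was tested with camera in limma with a preset correlation of 0.01, adjusted over the 34 lists with at least 3 tested genes, and again with an estimated correlation and with fry. Single members were also counted with p adjusted over the list alone. Each list's median was set against 10000 random lists matched on brightness in 50 bins. Genes of a random list are drawn independently, so a list's percentile is too extreme where its genes move together. The camera test with a preset correlation of 0.01 takes genes of a list as nearly independent, so its p is too small where they move together.

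The genes named in the text follow a rule fixed in the same way. Where fewer than 15 genes passed over all genes in a direction, those that passed and then the genes of smallest p up to 10 per direction were named as not having passed, together with the 2 to 4 members of smallest p of each list. For brevity, and after the values were seen, several lists with no call by camera were given 1 member, that of smallest p, or for basal keratinocytes KRT14 beside ITGB4, which is named with the basement membrane. Of probe sets without a single symbol the values of 2 per direction are given, with no ID. SLC25A28 was named after its values were seen, since it passed in a single alternative. The collagen genes COL1A1 and COL1A2 were also named after their values were seen.

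The procedure was tested on simulated data with 200 of 12519 probe sets changed, in 10 simulations of 3 arrays against 3. It recovered 8.2% of probe sets changed 2-fold, 73% of those changed 4-fold, 90.4% at 8-fold and 95% at 16-fold, with 6.8 false calls per simulation on average. A list shifted by 1 on the log2 scale was called in 10 of 10 simulations. The lists called in the real data had smaller medians, from 0.26 to 0.76. Probe sets were drawn independently and with no brightness trend, so the simulation does not test camera where genes of a list move together. Equal numbers were changed at each fold, so recovery may differ where changes are fewer or smaller.

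Alternatives planned in advance were 3 other filters on dim probe sets, quantile normalization, centring on the median, an intensity trend with robust variance, array weights, an ordinary linear model, the replicate number as a block, every probe set in place of genes, the mean of a gene's probe sets, an estimated correlation, and leaving out each array in turn. A set of 4 was added after the data were seen, namely cyclic loess, the hybridisation controls as a covariate, a fit without normal arrays 2 and 3, whose hybridisation controls were dimmest, and 64 added before log2. The fit without normal arrays 2 and 3 sets 3 laminitis arrays against normal 4 alone, so its spread comes from the laminitis arrays and normal 4 is assumed to vary like them. Adjustment over all list genes together was also added then.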

Results

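Transcript levels were measured in lamellar hoof tissue, the interleaved epidermis and dermis that suspends the coffin bone inside the hoof wall, with laminitis, the disease in which this attachment fails, and in normal equine tissue of the same kind. RNA from the right foot of 3 laminitis samples (replicates 1, 3 and 4) and 3 normal samples (replicates 2, 3 and 4) was hybridised to bovine GeneChips, 1 array per sample. The comparison asked which transcripts differ between diseased and normal lamellae. The arrays held 24016 probe sets besides the controls, of which 12519, for 6151 named genes, were bright enough to test. The median signal of an array lay between 86.7 and 96.6 on the deposited linear scale. The number of arrays limits the precision. The labels do not say whether the 6 samples came from separate horses, so the p-values measure only the spread between these samples, which may be technical.

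S100A9, S100A8, PTX3 and CFB, which act in innate defence, had the largest log2 differences among the genes named here on the deposited scale. S100A9 and S100A8, the subunits of the antimicrobial protein calprotectin, were 22.9-fold and 20.7-fold higher in laminitis, with log2 differences of 4.52 ± 0.87 and 4.37 ± 1.00 (SE, n = 3 per group). PTX3, a secreted pattern-recognition protein, was 28.9-fold higher (4.85 ± 0.79), and CFB, complement factor B, was 13.1-fold higher (3.71 ± 0.56). For each of these 4 genes every laminitis array lay above every normal array. None of them passed the test over all genes, where the limma adjusted p was 0.226 for S100A9, 0.296 for S100A8, 0.191 for PTX3 and 0.161 for CFB. The mean signal of S100A8 was 5948 in laminitis and 224 in normal tissue, and its values on the laminitis arrays were 7256, 9810 and 779. PTX3 and CFB were dim in normal tissue, with mean signals of 17.7 and 28.1, so the size of their folds depends on values below the array median. With 64 added to every signal before log2, a setting chosen after the data were seen, the log2 differences became 2.42 for PTX3, 2.28 for CFB, 3.52 for S100A9 and 3.94 for S100A8, and TNFRSF21, a death receptor, lay above CFB at 2.31. When 1 array was left out the log2 difference ranged from 3.98 without normal replicate 3 to 5.56 without normal replicate 4 for PTX3, from 4.03 to 5.33 for S100A9, from 3.69 to 5.52 for S100A8 and from 3.31 to 4.41 for CFB, in the last 3 genes lowest without laminitis replicate 1 and highest without laminitis replicate 4.

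**Figure D1:**
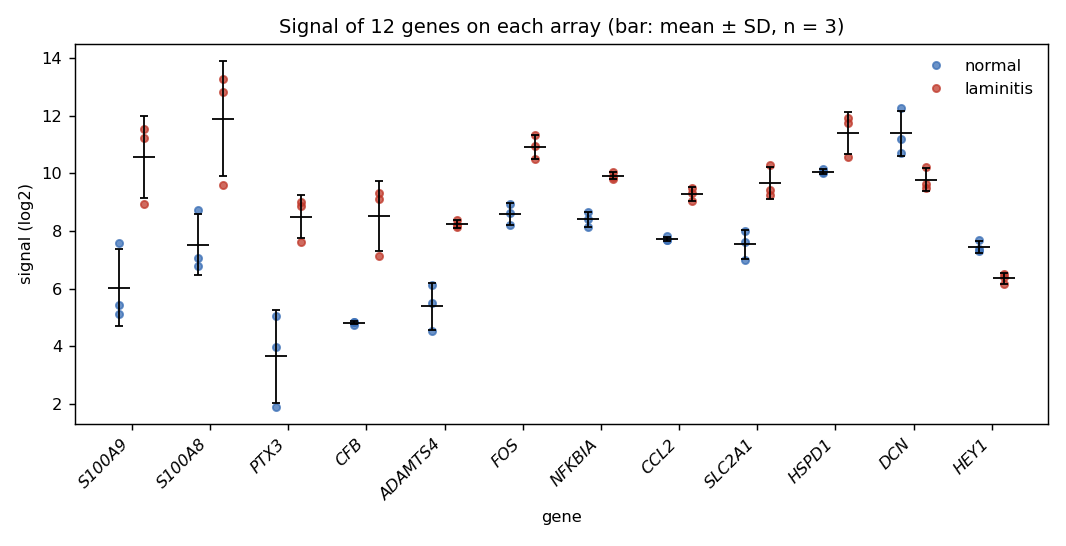
Log2 signal of 12 genes on each of the 3 laminitis and 3 normal arrays, with gene symbols on the horizontal axis, points for arrays and bars for the mean ± SD. S100A8 spread from 779 to 9810 in linear signal among the laminitis arrays, and all 12 genes had the 2 groups apart.

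Over all genes tested, limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower in laminitis, and 0 probe sets in either direction. The smallest adjusted p was 0.101. At an unadjusted p under 0.05, limma gave 324 genes higher and 278 lower, where 308 in all are expected by chance. At an unadjusted p under 0.01 there were 103 genes higher and 61 lower, against 62 in all expected by chance. The groups did not overlap for 1049 genes, or 17.1% of those tested, where chance gives 10%. Among these, 102 genes were at least 2-fold higher in the mean and 73 at least 2-fold lower. With an intensity-dependent prior and robust variance in limma, 4 genes passed as higher, namely FOS, CCL2, PNRC1 and ZFAND5, each at an adjusted p of 0.0435. The ordinary linear model, with no variance shared between probe sets, called 0.

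The 10 genes of smallest p among the higher ones had every laminitis array above every normal array, and none passed in limma over all genes. DKK1, a secreted Wnt antagonist, was 5.92-fold higher (log2 2.57 ± 0.29, limma adjusted p 0.101). The transcription factor subunit FOS was 5.05-fold higher (2.34 ± 0.30), with mean signals of 2002 in laminitis and 394 in normal tissue, while a dimmer FOS probe set gave -0.017. CCL2, a monocyte chemoattractant, was 2.94-fold higher (1.55 ± 0.20), and the nuclear receptor coactivator PNRC1 had a log2 difference of 1.59 ± 0.21. Another CCL2 probe set gave 0.84 ± 0.29, and other PNRC1 probe sets gave 1.84 and 1.10. C10H15orf48 was 5.72-fold higher (2.52 ± 0.32). FOS, CCL2, PNRC1 and C10H15orf48 shared a limma adjusted p of 0.131. ADAMTS4, an aggrecan-cleaving protease, was 7.24-fold higher (2.86 ± 0.40), and ZFAND5, a zinc finger protein of the ubiquitin system, was 3.68-fold higher (1.88 ± 0.25). NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, was 2.86-fold higher (1.52 ± 0.21). ADAMTS4, ZFAND5 and NFKBIA had limma adjusted p of 0.136. The death receptor TNFRSF21 was 7.03-fold higher (2.81 ± 0.41, limma adjusted p 0.154), and casein kinase CSNK1A1 was 3.04-fold higher (1.61 ± 0.24, limma adjusted p 0.161). The normal means of DKK1, C10H15orf48 and ADAMTS4 were 20.4, 35.6 and 46.3, below every array's median, and with 64 added their log2 differences were 1.12, 1.40 and 1.76. Among other CSNK1A1 probe sets the log2 difference ranged from -0.072 to 1.06.

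The 10 genes of smallest p among the lower ones also kept the groups apart without passing over all genes. OXNAD1 had a log2 difference of -2.08 ± 0.36 (limma adjusted p 0.198) and CFDP2 of -1.43 ± 0.24 (limma adjusted p 0.193). HEY1, a transcriptional target of Notch signalling, had -1.09 ± 0.21, and NTN4, a netrin found in basement membranes, had -1.10 ± 0.21. KCNJ2, an inward-rectifier potassium channel, had -1.76 ± 0.34. CDH2, the adhesion molecule N-cadherin, had -2.29 ± 0.47, and the actin cross-linker FLNC had -2.13 ± 0.44. LOC518526, SYNE1 and ZFYVE1 had -1.11, -1.52 and -1.48, while another SYNE1 probe set gave -0.17. The laminitis means of 7 of these 10 genes, from 28.0 for CDH2 to 82.4 for HEY1, lay below every array's median, and with 64 added the differences of the 10 genes ranged from -1.16 for SYNE1 to -0.67 for NTN4. Limma adjusted p of the 8 genes other than OXNAD1 and CFDP2 ranged from 0.222 to 0.254. Among probe sets with no single gene symbol, the 2 of smallest p among the higher ones had log2 differences of 2.04 ± 0.21 and 2.35 ± 0.24, and the 2 among the lower ones -2.40 ± 0.26 and -2.35 ± 0.26, each at a limma adjusted p of 0.101.

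The 35 gene lists, fixed before the data were examined, held 796 distinct genes, of which 400 were tested. Within its own list, with p adjusted over the list alone by Benjamini-Hochberg in limma, 20 genes were called higher and 2 lower, against 0 over all genes. The normal means of BIRC3, CYBB and ZFP36, which are among them, were 74.2, 61.7 and 54.8, below every array's median, and with 64 added their log2 differences were 1.40, 1.37 and 0.99. Adjusted over the 400 list genes together, a step chosen after the data were seen, limma called 11 higher and 0 lower. These 11 were ADAMTS4, BIRC3, CCL2, CFB, CYBB, FOS, MT2A, NFKBIA, PTX3, S100A9 and SLC2A1. The camera test, which asks whether a list lies higher or lower than the other genes, could be run on 34 lists and called 5 higher and 0 lower. With the correlation within each list estimated from these arrays it called 0 lists, and the smallest adjusted p from fry, a rotation test of whether a list moves on balance in a direction, was 0.139.

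The antimicrobial and acute-phase list had 6 tested members, of which 3 rose adjusted over the list alone and 0 over all genes. S100A9, S100A8 and SAA3, an acute-phase serum amyloid, had limma p adjusted over the list alone of 0.00737, 0.00977 and 0.0129, and SAA3 was 2.78-fold higher (log2 1.48 ± 0.39). The defensin DEFB4A lay at 0.052 ± 0.35, S100A7 at 0.027 ± 0.34 and CP at -0.00062 ± 0.31, so the list's median falls between SAA3 and DEFB4A. Over its 6 members the antimicrobial median was 0.76 (camera adjusted p = 0.0149, and adjusted p = 0.695 with an estimated correlation). The call was lost without normal replicate 4 (median 0.58, camera adjusted p 0.467), and with no filter on dim probe sets, which takes in all 16 members with a probe set, the median changed sign to -0.13 (camera adjusted p 0.895). Among NF-kB targets and endothelial adhesion genes, 4 of 13 rose adjusted over the list alone, namely NFKBIA, BIRC3, PTX3 and NFKB2, and 0 over all genes. BIRC3, an inhibitor of apoptosis, was 4.12-fold higher (2.04 ± 0.31), and NFKB2, an NF-kB subunit, was 1.91-fold higher (0.94 ± 0.24). That list's median was -0.058 while its mean was 0.54, and camera pointed up with an adjusted p of 0.277.

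CCL2 was the member of 13 cytokines and chemokines that rose adjusted over the list alone, with 0 over all genes. IL1RN, the interleukin-1 receptor antagonist, had -1.92 ± 0.60, or -2.64 to -1.37 with 1 array left out. Its laminitis mean signal of 46.3 lay below every array's median, and with 64 added the difference was -0.91. CCL3 had -0.58 ± 0.21, with 0.094 by another probe set, and IL1B had 0.55 ± 0.25. The list's median was -0.034 and its mean 0.0062, and camera pointed up with an adjusted p of 0.92. CFB was 1 of 10 tested complement genes and the only member to rise adjusted over the list alone, again with 0 over all genes; CFI, a complement inhibitor, had -0.74 ± 0.27. The complement median was -0.084 and the mean 0.27, with camera pointing down at an adjusted p of 0.914. Of 10 interferon-response genes 0 passed either way, with RSAD2 at 0.65 ± 0.27 and STAT2 at -0.44 ± 0.20, and the median was -0.19 (camera adjusted p 0.434). Of 12 coagulation and fibrinolysis genes 0 passed either way, with ANXA2 at 0.74 ± 0.22 and PROS1 at -0.68 ± 0.24 (median 0.045, camera adjusted p 0.781).

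ADAMTS4 was the member of 10 extracellular matrix proteases that rose adjusted over the list alone (limma p 0.00174), with 0 over all genes, while MMP19 had -0.70 ± 0.41 and ADAM10 0.50 ± 0.28, with 0.090 by another ADAM10 probe set. The protease list had a median of -0.096 and a mean of 0.19, and camera pointed up with an adjusted p of 0.781. CST3, cystatin C, rose 2.23-fold adjusted over the list alone among 10 protease inhibitors (log2 1.16 ± 0.23, limma p 0.0151), with 0 members over all genes. Other CST3 probe sets gave 0.46 and -0.27, and TIMP2 had -0.34 ± 0.30, with 0.26 and -0.037 by its other probe sets. The inhibitor list's median was 0.020 (camera adjusted p 0.861).

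Among 22 tested heat shock and unfolded protein response genes 18 had a positive log2 difference, and 0 passed singly, either adjusted over the list alone or over all genes. The mitochondrial chaperone HSPD1 had 1.34 ± 0.36, the endoplasmic reticulum chaperone HSP90B1 had 1.54 ± 0.50, the cytosolic HSP90AA1 had 1.08 ± 0.36, and the small heat shock protein HSPB1 had 1.00 ± 0.34. The heat shock median was 0.39 (camera adjusted p = 0.00113, and adjusted p = 0.695 with an estimated correlation). After quantile normalization the median was 0.28, at a camera adjusted p of 0.00839. As deposited, the list's median on laminitis replicates 3, 1 and 4 lay at 0.601, 0.273 and 0.022 above the mean over arrays. On the normal arrays it lay between -0.355 and -0.052. Of 21 hypoxia-inducible and glycolytic genes 3 rose adjusted over the list alone and 0 over all genes. These were the glucose transporter SLC2A1, 4.38-fold higher (2.13 ± 0.37), the mTOR inhibitor DDIT4, 2.34-fold higher (1.22 ± 0.28), and the glycolytic enzyme GAPDH, 1.87-fold higher (0.90 ± 0.23), with HK1 at 0.80 ± 0.29. The hypoxia median was 0.34 (camera adjusted p = 0.00637, and adjusted p = 0.695 with an estimated correlation). Camera no longer called it without laminitis replicate 1, at a median of 0.28 and an adjusted p of 0.115, or after quantile normalization, at 0.22 and 0.0658.

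Of 16 immediate early genes, which respond to stimuli without new protein synthesis, 3 rose adjusted over the list alone and 0 over all genes. Besides FOS these were ZFP36, which destabilises cytokine transcripts (1.72 ± 0.43), and the orphan nuclear receptor NR4A2, 2.82-fold higher, and FOSL1 had 0.93 ± 0.31. The immediate early median was 0.26 (camera adjusted p = 0.0174, and adjusted p = 0.695 with an estimated correlation). Camera no longer called it after quantile normalization, at a median of 0.19 and an adjusted p of 0.0658, without laminitis replicate 1 (0.17, 0.115), without laminitis replicate 4, where the median was larger (0.31, 0.0695), or without normal replicate 2 (0.14, 0.117). Among 10 glucocorticoid-inducible genes, GLUL (1.28 ± 0.30) and the metallothionein MT2A (1.01 ± 0.20) rose and CDKN1C, a cell cycle inhibitor, fell by 1.36 ± 0.36 on the log2 scale, all adjusted over the list alone, with 0 over all genes. A dimmer CDKN1C probe set gave -0.13. The list's median was 0.32 (camera adjusted p 0.168). MT2A was also the 1 of 17 oxidative stress and metallothionein genes that rose adjusted over the list alone, with 0 over all genes and PRDX6 at 0.41 ± 0.20. That list had a median of 0.012 and a mean of -0.056 (camera adjusted p 0.765).

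The structural lists had 0 members past the test, adjusted over the list alone or over all genes. Of 12 basement membrane and hemidesmosome genes, HSPG2, perlecan, had -0.75 ± 0.18, with a limma p of 0.0548 adjusted over the list alone, and ITGB4, a hemidesmosome integrin, had 1.29 ± 0.57, or 0.76 to 1.75 with 1 array left out (median -0.089, camera adjusted p 0.861). Of 8 desmosome and adherens junction genes, CTNNB1 had 0.36 ± 0.17, or a negative value after cyclic loess normalization, and PKP2 had -0.29 ± 0.17 (median -0.16, camera adjusted p 0.765). Of 11 keratins, KRT8 had -0.49 ± 0.20 and KRT17 0.60 ± 0.32 (median -0.13, camera adjusted p 0.861). The 3 tested cornified envelope genes had a median of -0.23, with ELOVL4 at -0.88 ± 0.54 and ALOX12B at 0.90 ± 0.59 (camera adjusted p 0.861). In the dermal matrix and fibroblast list of 24 genes, 15 had a negative log2 difference. DCN, the collagen-binding proteoglycan decorin, had -1.61 ± 0.42, with mean signals of 903 in laminitis and 2982 in normal tissue, MFAP4 had -0.58 ± 0.24, and the median was -0.23 (camera adjusted p 0.254). The list's median lay on normal replicate 4 at 0.66 above the mean over arrays and on the other arrays between -0.33 and 0.068. Leaving out 1 array moved the median to -0.016 without laminitis replicate 1 (camera adjusted p 0.787) and -0.12 without normal replicate 4 (0.929), while camera called the list lower without normal replicate 2 (-0.36, 0.0131) or normal replicate 3 (-0.31, 0.0318).

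Camera called 0 of the 12 cell type lists it could test. Of 9 tested neutrophil markers S100A9 and S100A8 rose adjusted over the list alone and 0 over all genes, while ELANE, neutrophil elastase, had -1.05 ± 0.34 and MPO, myeloperoxidase, -0.44 ± 0.21. The neutrophil list's median was -0.078 and its mean 0.73, with camera pointing down at an adjusted p of 0.92. Of 8 monocyte and macrophage markers CYBB, a subunit of the phagocyte oxidase, rose 4.59-fold adjusted over the list alone (2.20 ± 0.41, limma p 0.00795), with 0 over all genes and MSR1 at 0.59 ± 0.27. That list's median was -0.025 and its mean 0.27, with camera pointing up at an adjusted p of 0.668. FABP4, a fatty acid binding protein of adipocytes and capillaries, fell by 0.88 ± 0.26 on the log2 scale as 1 of 2 adipocyte markers tested (limma p 0.0242 adjusted over the list alone), with 0 over all genes. Its mean log2 signal in laminitis, 6.26, lay below every array's median. Camera was not run on the 2 adipocyte markers.

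In the remaining cell type lists 0 members passed, adjusted over the list alone or over all genes. Of 12 T and NK cell markers, CD2 had -0.98 ± 0.38 and CD247 -0.81 ± 0.32 (median -0.094, camera adjusted p 0.434). The 5 B and plasma cell markers had a median of -0.26, with JCHAIN at 0.47 ± 0.33 (camera adjusted p 0.668). The medians were -0.12 for 10 endothelial markers, with ROBO4 at -0.52 ± 0.31 (camera adjusted p 0.668), and -0.16 for 8 smooth muscle and pericyte markers, with TAGLN at -0.83 ± 0.34 (camera adjusted p 0.434). Nerve and Schwann cell markers (7 tested, NGFR at -0.93 ± 0.40) had a median of -0.31 at a camera adjusted p of 0.436. The laminitis means of ELANE and NGFR, 64.3 and 65.3, lay below every array's median, and with 64 added their differences were -0.59 and -0.50. The 8 skeletal muscle markers had a median of -0.017 (MB at -0.21 ± 0.21, camera adjusted p 0.92). The 8 bone and cartilage markers had a median of -0.17 and a mean of 0.014, with COL11A1 at 1.13 ± 0.69, or 0.49 to 1.79 with 1 array left out and -0.31 by another probe set (camera pointing down, adjusted p 0.781). The 3 blood and erythroid markers had a median of -0.095 (EPB42 at -0.46 ± 0.58, or -1.07 to -0.078 with 1 array left out, camera adjusted p 0.781), and the 3 melanocyte markers had 0.29 (KIT at 0.29 ± 0.24, with -0.22 and 0.012 by other probe sets, camera adjusted p 0.668). The 6 basal keratinocyte markers had a median of 0.054, with KRT14 at 0.60 ± 0.50, or 0.0040 to 1.05 with 1 array left out (camera adjusted p 0.668).

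Of 39 tested cytosolic ribosomal protein genes, 37 had a positive log2 difference and 0 passed singly, adjusted over the list alone or over all genes. RPS12 had 0.78 ± 0.19 and RPL4 0.68 ± 0.18, while other RPS12 probe sets gave -0.058, -0.19 and, for a dim one, -2.57. The ribosomal median was 0.34 (camera adjusted p = 4.3e-10, and adjusted p = 0.695 with an estimated correlation). After quantile normalization the median was -0.021 and the camera adjusted p 0.956. Log2 differences ran with brightness, from a median of -0.19 in the dimmest 10% of tested probe sets to 0.19 in the brightest 10%. Of 31 oxidative phosphorylation genes 0 passed either way, with UQCRB at -0.59 ± 0.18 and ATP5F1B at 0.49 ± 0.20 (median 0.047, camera adjusted p 0.861). The 14 cell cycle genes had 0 passing either way and a median of -0.13, with BIRC5 at -0.52 ± 0.24 (camera adjusted p 0.668), and the 10 insulin and IGF axis genes had 0 passing and a median of 0.13, with IGFBP2 at 0.48 ± 0.27 (camera adjusted p 0.668). Medians near 0 changed sign after quantile normalization for cytokines (0.059), monocyte markers (0.041), skeletal muscle markers (0.020), protease inhibitors (-0.082), oxidative stress genes (-0.0092) and oxidative phosphorylation genes (-0.011), none of them called.

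**Figure D2:**
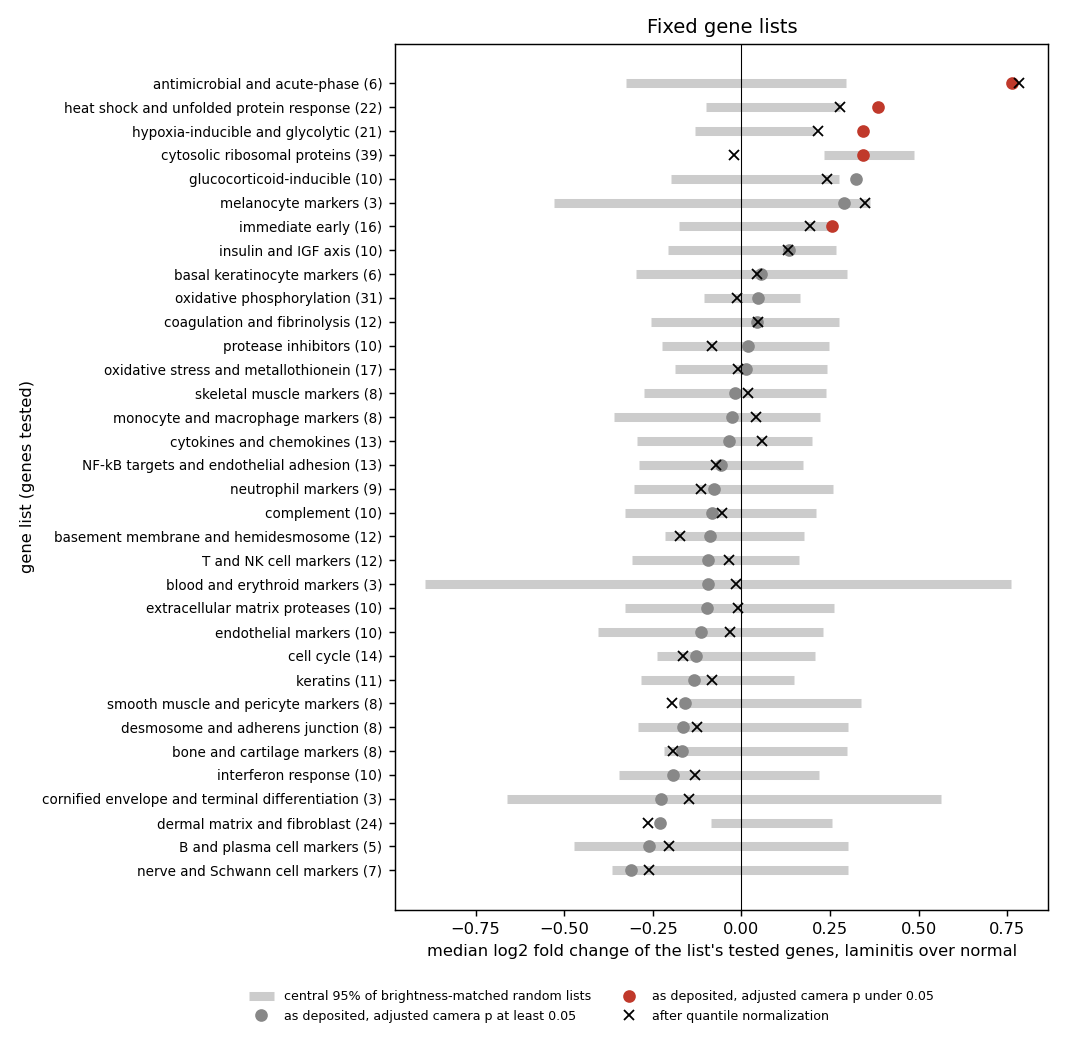
Median log2 difference, laminitis over normal, of the tested genes of each of 34 lists (number tested in brackets), as deposited (filled circles) and after quantile normalization (crosses), with grey bars for the central 95% of 10000 random lists of equally bright genes. Of the 5 lists that camera called as deposited, shown in red, the ribosomal protein and immediate early lists lay inside their grey bars, and the ribosomal cross lay at -0.021.

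**Figure D3:**
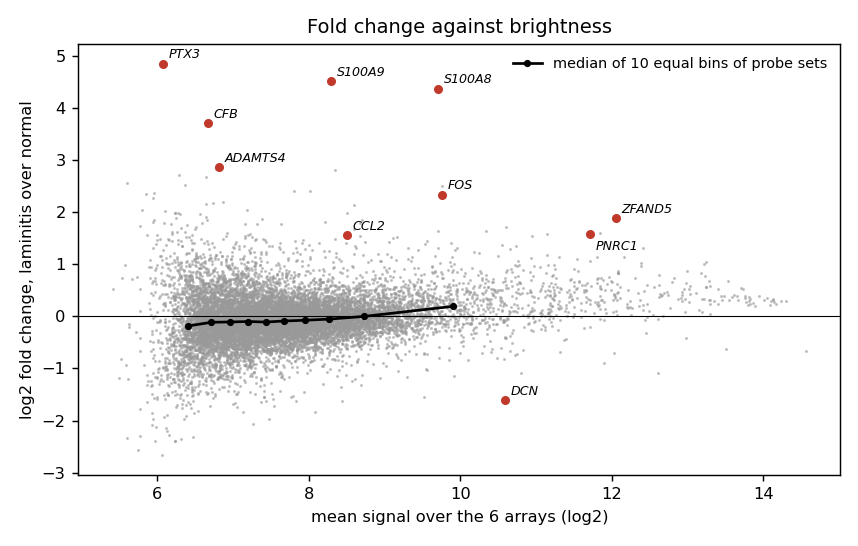
Log2 difference of each tested probe set against its mean log2 signal over the 6 arrays, with 10 genes marked in red and a black line through the medians of 10 equal bins of probe sets. The line ran from -0.19 at the dim end to 0.19 at the bright end.

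Over tested probe sets Pearson's r averaged 0.839 between laminitis arrays (0.822 to 0.848), 0.864 between normal arrays (0.855 to 0.878) and 0.829 across the groups (0.805 to 0.850). Laminitis replicate 4 correlated with the normal arrays at 0.844 to 0.850 and with the other laminitis arrays at 0.848 and 0.822. Components 1 and 2 held 31.3% and 21.4% of the variance. The 18 hybridisation control probe sets, which report RNA added to every array at set amounts, were 1.45-fold brighter on the laminitis arrays (log2 means 11.3 ± 0.052 and 10.7 ± 0.30, SD, n = 3 per group; exact two-sided permutation p 0.1, the smallest that 3 against 3 can give). With their mean as a covariate, a setting chosen after the data were seen, the heat shock median was 0.26 (camera adjusted p 0.439), the immediate early median -0.042 (0.953) and the hypoxia median 0.40 (0.0695), while the antimicrobial median was 1.55 (0.000301) and the ribosomal median 0.27 (0.0208). These controls ran with the groups. Within the groups they differed mainly between normal replicate 4 and normal replicates 2 and 3, so this fit leans on normal replicate 4. On laminitis replicate 1 the spiked-in poly-A controls had a 3' minus 5' log2 signal of 2.5, against 0.67 to 0.89 on the other arrays. The 3' minus 5' difference of actin was 2.41 ± 0.28 in laminitis and 1.93 ± 0.81 in normal tissue (SD, n = 3 per group, exact two-sided permutation p 0.4), and that of GAPDH was 2.52 ± 0.67 and 2.67 ± 0.18 (exact two-sided permutation p 0.8).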

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

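The tests of gene counts over other splits of the arrays were chosen after the result was seen, as were the covariate for the hybridisation controls, the fit without normal arrays 2 and 3, and the spread of list medians between arrays.

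Control probe sets, left out of the planned test of genes, differed between the arrays. The hybridisation controls were used only in the added fits, as a covariate and to pick normal arrays 2 and 3. The 18 hybridisation control probe sets were brighter on every laminitis array than on every normal array, by 0.535 on the log2 scale, with means of 11.22, 11.25 and 11.32 against 10.58, 10.53 and 11.07. The poly-A spike-ins on laminitis replicate 1 had a 3' minus 5' log2 signal of 2.5, and the 5' probe set of the dap spike-in read 378 there against 2240 to 3220 on the other arrays.

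A pattern weighed here is that camera called 5 lists higher in laminitis while log2 differences ran with brightness, so a single scaling factor per array could raise lists of bright genes. The ribosomal list's median lay at the 51.08 percentile of random lists of equally bright genes and went from 0.34 to -0.021 after quantile normalization (adjusted p 0.956), which is consistent with the brightness trend. The antimicrobial median lay at percentile 100 and the heat shock median at 99.86, and camera called both after quantile normalization (adjusted p 0.00839 for each), which argues against the trend as the whole cause. These percentiles are too extreme where genes of a list move together, and the estimated correlation was 0.42 and 0.041. After quantile normalization the per-array medians of the antimicrobial and heat shock lists differed between the groups by 0.849 (SE between arrays 0.279) and 0.391 (SE 0.175). The heat shock list then lay at 0.53 on laminitis replicate 3 but at 0.099 and 0.020 on replicates 1 and 4, against -0.281 to -0.029 on the normal arrays. The hypoxia list at percentile 99.92 and the immediate early list at 96.93 lost their calls, at a camera adjusted p of 0.0658. Their medians shrank from 0.34 to 0.22 and from 0.26 to 0.19. The per-array list median difference went from 0.267 (SE between arrays 0.147) to 0.207 (SE 0.11) for hypoxia. For the immediate early list it went from 0.248 (SE 0.147) to 0.231 (SE 0.152). With the calls lost and these values, the trend stays open for both lists. Without laminitis replicate 1 camera called 3 of the 5 lists, and of the 6 arrays only this one ended the hypoxia call (median 0.28 in place of 0.34, adjusted p 0.115), with that list at 0.44 on it against -0.012 and 0.055 on the other laminitis arrays, while the immediate early call (0.17 in place of 0.26, 0.115) was also lost without laminitis replicate 4 (0.0695) or normal replicate 2 (0.117), so the part of that array stays open. Laminitis itself stays an open explanation for the antimicrobial and heat shock lists, with the limit that neither was called by camera with an estimated correlation (adjusted p 0.695). The heat shock list was also not called with the hybridisation controls, which run with the groups, as a covariate (camera adjusted p 0.439). The antimicrobial list was also not called with no filter on dim probe sets (camera adjusted p 0.895), with the ordinary linear model or without normal replicate 4.

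The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.01 limma gave 164 genes for the real split and 82 for the highest of the others, so 1 of the 10 splits gave as many. Camera called 5 lists for the real split and 3 for the highest other, again with 1 of 10 as large. After Benjamini-Hochberg adjustment limma called 0 genes in the real split and 0 in the highest other. With 0 in the real split, 10 of 10 splits are as large whatever they hold, so this count decides nothing.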

How the results depend on the processing

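Cyclic loess, the hybridisation controls as a covariate, the fit without normal arrays 2 and 3 and 64 added before log2 were chosen after the result was seen. The fit without normal arrays 2 and 3 leaves normal 4 alone against 3 laminitis arrays and assumes that it varies as they do, so its values show what sets that array apart. The hybridisation covariate runs with the groups and also leans on normal 4. The count of 0 genes lower after limma's Benjamini-Hochberg adjustment, also at 2-fold or more, held under every alternative run. The count of 0 genes higher became 4 with an intensity trend and robust variance (FOS, CCL2, PNRC1 and ZFAND5, all at least 2-fold), and ranged from 0 to 2 when 1 array was left out, with 2 without laminitis replicate 4, namely CFB (adjusted p 0.009) and SLC25A28 (adjusted p 0.0453), both at least 2-fold. The naming rule, with up to 4 members per list, picked 144 genes, not all of which are named in the text. Of these 144 the sign changed for 19 with the hybridisation covariate, 12 without normal arrays 2 and 3, 5 with cyclic loess and 2 with quantile normalization. Those changed by the hybridisation covariate include HK1, ADAM10, COL11A1, ELOVL4, JCHAIN, KIT and MB. Signal over background limits what can be said of dim genes, since with 64 added before log2 the DKK1 difference was 1.12 in place of 2.57. The cause was not tested for the changes below unless stated.

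Genes at an unadjusted p under 0.01 numbered 103 higher and 61 lower. Counting every probe set, which takes more items, gave 193 and 132. The hybridisation covariate gave 15 lower, the fit without normal arrays 2 and 3 gave 6 lower with fewer samples, and the 75th percentile filter gave 33 lower with fewer genes tested. Leaving out 1 array gave 58 to 128 higher (58 without laminitis 3, 65 without laminitis 1 and 65 without normal 3) and 21 to 105 lower (105 without laminitis 4, 24, 21 and 23 without normal 2, 3 and 4).

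With replicate number as a block, which pairs arrays 3 and 4 of both groups, 65 genes were higher and 37 lower at that threshold and camera called 3 lists. The hypoxia median became 0.070 and the immediate early median 0.11, neither called. Laminitis 1 and normal 2 each have a block to themselves, so this fit takes the group difference from replicates 3 and 4 alone. The numbers were not taken to pair the samples, since deviations of same-numbered arrays correlated at -0.017 and -0.031.

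Camera called 5 lists higher in the planned test. It called 2 after quantile normalization, 2 after cyclic loess, 2 with the hybridisation covariate, 3 with the ordinary linear model, 3 without normal arrays 2 and 3, 0 with an estimated correlation, and 3 to 5 when 1 array was left out (3 without laminitis 1). It called 0 lists lower, but 1, the dermal matrix list, with the 75th percentile filter (median -0.28), the hybridisation covariate (-1.21), and without normal arrays 2 and 3 (-0.82), and 0 to 1 when 1 array was left out (1 without normal 2 or normal 3).

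The ribosomal median of 0.34 reversed to -0.021 after quantile normalization and -0.048 after cyclic loess, both of which remove the brightness trend by construction, was 0.34 and not called with an estimated correlation, and ranged from 0.27 to 0.40 without 1 array. The heat shock median was not called with an estimated correlation (0.39), with the hybridisation covariate (0.26) or without normal arrays 2 and 3 (0.23), and ranged from 0.28 to 0.49 without 1 array, called each time. The hypoxia median was not called after quantile normalization (0.22), cyclic loess (0.28), with the hybridisation covariate (0.40) or an estimated correlation (0.34), and ranged from 0.23 to 0.36 without 1 array, not called without laminitis 1 (0.28). The antimicrobial median changed sign to -0.13 with no filter, where more members were tested and camera still pointed up, and was not called there, with the ordinary linear model (0.76) or with an estimated correlation (0.76), and it ranged from 0.58 to 0.96 without 1 array, not called without normal 4 (0.58). The immediate early median was not called with the 75th percentile filter (0.20), the filter on the mean (0.20), quantile normalization (0.19), the ordinary linear model (0.26), an estimated correlation (0.26), cyclic loess (0.22), the hybridisation covariate (-0.042) or without normal arrays 2 and 3 (0.042), and ranged from 0.14 to 0.44 without 1 array, not called without laminitis 1 (0.17), laminitis 4 (0.31) or normal 2 (0.14).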

Other observations

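The tests of neutrophil RNA and of dermis were chosen after the result was seen.

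Laminitis replicate 4 lay below the other laminitis arrays in several genes, chosen after their values were seen and not tested. Signals on laminitis replicates 3, 1 and 4 were 2392, 2947 and 486 for S100A9, 556, 640 and 139 for CFB, 722, 720 and 266 for SLC25A28, a mitochondrial iron transporter, 3883, 3412 and 1523 for the chaperone HSPD1, and 3774, 6275 and 1606 for the chaperone HSP90B1. Other genes did not show this order, with 1443, 2593 and 1969 for FOS, 265, 233 and 256 for CYBB and 148, 149 and 256 for DEFB4A. On component 1 of the 6 arrays laminitis replicates 3, 1 and 4 lay at -24.9, -52.3 and 7.61, and the normal arrays between 19.5 and 29.3.

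The rise of S100A8 and S100A9 may come from more neutrophil RNA in the laminitis samples, which would also raise other neutrophil transcripts. The other 7 tested neutrophil markers had a median log2 difference of -0.252, ranging from -1.05 for ELANE to -0.012, so none showed a rise. CYBB, a subunit of the phagocyte oxidase counted with the monocyte markers and not among these 7, was 4.59-fold higher. Whether neutrophils in this tissue hold the transcripts of all 7 markers was not tested. An SE of 0.136 taken over the 7 genes measures the spread between genes and not between samples. Only 3 of these 7 were brighter than the 75th percentile of the arrays, so the bovine probes for the rest may not read the horse transcripts, and the explanation stays open. S100A8 and S100A9 are also in the antimicrobial list and are made by stressed keratinocytes, a source within this tissue that was not tested. Laminitis as the cause of a change within resident cells also stays untested.

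The dermal matrix and fibroblast median of -0.23 lay at the 0.03 percentile of equally bright random lists. Less dermis in the laminitis samples is a candidate explanation. That percentile is too extreme where genes of the list move together. The estimated correlation within the list was 0.27, and with it the camera adjusted p was 0.859. Of its 24 tested genes 9 had a positive log2 difference. Among these, COL1A1 and COL1A2, picked after their values were seen, had 0.31 ± 0.74 and 0.35 ± 0.85. The 25 tested markers of endothelium, smooth muscle and pericytes, and nerve together had a median of -0.15, at percentile 6.26 of equally bright lists. Some of these random lists lay lower still, so the value is compatible with no change in dermis. It does not decide between less dermis and no change. Normal replicate 4 stood highest for the matrix list, and without it the median was -0.12 (camera adjusted p 0.929), so a tissue piece with more dermis in that sample could also account for the list. The median was -0.016 without laminitis replicate 1 (camera adjusted p 0.787), while camera called the list lower without normal replicate 2 (-0.36, 0.0131), without normal replicate 3 (-0.31, 0.0318), with the 75th percentile filter (-0.28, 0.0497) and with the hybridisation covariate (-1.21, 1.71e-06). That covariate runs with the groups and within them mainly sets normal replicate 4 apart, so its value leans on that same array. A change of matrix genes in laminitis itself stays untested.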
